A study of Mus musculus with 6 samples.

How the data were processed

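RNA sequencing was compared between lipid-droplet-low and lipid-droplet-high microglia from the hippocampus of young male C57BL/6 mice given lipopolysaccharide (LPS), a bacterial cell wall component that provokes inflammation. Per the labels, mice were 3 months old and received 1 mg/kg LPS into the peritoneum for 4 days, and tissue was taken 24 h after the last injection. Hippocampi of 2 mice were pooled for each sample. About 10000 live cells positive for CD11b and low for CD45, the usual gate for microglia, were sorted, and BODIPY, a dye of neutral lipids, parted them into a low and a high gate. Each gate had 3 libraries, made per the labels' protocols from total RNA with the Smart-seq v4 kit for small inputs and the Nextera XT kit. Neither kit keeps the strand of the transcript. Libraries of mice given saline were not analysed here.

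Per the series' design text, the authors checked reads with FastQC 0.11.4, aligned them to the mouse genome build mm10 with STAR 2.5.3a, counted reads per gene with the counting option of STAR and tested genes with DESeq2 at its standard settings. The submitters' processing notes list both mm9 and mm10. The gene annotation used for counting and the strand column taken were not given in the sources used here. The deposited table held 1 normalized signal value per gene and library, which are gene counts that the authors divided by a size factor per library. It listed 15912 genes, of which 50 were at 0 in every library. The names of 23 genes had been turned into dates by spreadsheet software, which gave 2 repeated names over 4 rows, and none of these genes is named in the text. Results of some single genes that the rule below selects are not reported here. Of the gene symbols, 15281 were found in GENCODE release M21 and 15141 in RefSeq. Mitochondrially encoded genes were not analysed here, so the planned comparison of their share between gates was not made, and the list of these genes has no value.

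Every deposited value of a library was a whole multiple of 1 step within a tolerance of 0.05 of a read (100% of values in each library), and dividing by the step recovered whole reads. The recovered totals were 34899413, 36518323 and 35348360 reads for BODIPY-low libraries 1, 2 and 3, and 37688682, 37633089 and 39220494 for BODIPY-high libraries 1, 2 and 3. The size factors ran from 0.911 to 1.09. A count of 0 allows up to 3 reads, which was worth 2.76 to 3.29 normalized counts, depending on the library. Reads copied by PCR without molecular identifiers are not independent molecules, so intervals and this floor cover counting error only. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom was at least 29.1, and each library was counted as 1 sample.

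The main test was limma-trend (limma 3.58.1 in R 4.3.3), two-sided, on log2(normalized count + 1) with the gate as the only term. The standard settings that the authors name do not say which terms their model held. A gene entered with a normalized count of at least 10 in at least 3 of the 6 libraries, which kept 12767 genes. Adjusted p is the Benjamini-Hochberg value over these genes, and a call is an adjusted p under 0.05. Fold changes on this scale understate the change of genes with few reads, so means and ratios of recovered reads are given beside them. Means carry the SD over 3 libraries, and all adjusted p of genes come from this limma test unless another is named. The labels do not say whether the samples of a gate are separate pools of animals from one another, so p-values measure the spread between these samples.

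The lists of genes were fixed before the data were examined: 39 lists, of which 25 cover functions and states of microglia and 14 hold markers of other cells that the gate could hold. Lists with at least 5 tested genes (34) were tested with camera at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 34 lists. Camera asks whether the genes of a list rank higher or lower than all other genes. With the correlation between genes estimated from the 6 libraries, no list of the 34 passed, and the adjusted p from that version follows each list call of the main test. It was also computed with the block, but not with a library left out or other settings, so list calls named there rest on the preset correlation alone. Members past the gene test are counted over all genes tested and, where said, adjusted over the list alone.

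Named genes followed a rule fixed at the same time. It took the 12 genes of largest change in each direction among called genes with a mean of at least 50 and no overlap between gates, leaving out predicted genes. Only 3 genes were called lower, so 5 genes of smallest p filled that direction up to 8. It also took up to 4 members of smallest p from each list, and Plin2, Plin3, Apoe, Trem2, Tmem119, P2ry12, Cx3cr1, Il1b, Tnf, Cat, Slc33a1, Grn, Cd36, Acsl1 and Dgat2 always. The rule gave 175 genes, of which 47 passed the gene test. Other genes that complete a small count were named after their values were seen: Ctsd, Cd163, Clec10a, Pf4, Gfap, Gja1, Folr2, Ms4a7, Cbr2, Folr1, Itgax, C3, Clec7a, Axl, Rhob, Fau, H2-Ab1, H2-Eb1, Ccl3, Bub1, Rrm2, Nusap1, Ccna2, Kl, Adgre1, Aplp2, Vcam1, Stom, Slc22a17 and Clic4.

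Libraries of both gates carry the numbers 1 to 3. Deviations from the gate means correlated across genes at 0.354, 0.244 and 0.363 for samples of the same number, and at -0.255 to -0.095 for samples of different numbers. All 3 were above the limit of 0.1 set before calls were compared, so the numbers were taken to pair the samples; the pairing comes from the data, as the labels do not say what a number marks. A fit with the number as a replicate block was run as an alternative, and it is named in the text where it added calls in a list or among the named genes. It removed 0 calls among the named genes. The runs with 1 library left out had no block. Called genes lost in such runs passed limma with the block and all libraries, among them Mrc1 (adjusted p = 8.47e-07), Cd36 (1.51e-05), Igf1 (9.1e-05) and Lilrb4a (0.000118).

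Positions of genes are from GENCODE M21 on GRCm38, the same assembly as mm10. Of the 47 called named genes, 16 have exons that overlap those of another annotated gene on the opposite strand, and 4 of these also on the same strand. Reads of such neighbours cannot be told apart where the kit keeps no strand. Members of the ribosomal protein, MHC, glutathione transferase and leukocyte immunoglobulin-like receptor families have near-identical copies, and their counts are uncertain to that extent.

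Alternatives were other pseudocounts (0.5 and 5), no filter or a minimum of 50, TMM rescaling, quantile normalization, limma without a trend or with library weights, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, the replicate block with each of these tests, fry and an estimated correlation for lists, and leaving out each library or each number. Reads thinned to the smallest library, a test without the marker genes of other cells, and further fits with the block were added after the data were seen.

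The tests were checked on simulated counts for the comparison of BODIPY-high with BODIPY-low libraries, in 3 runs of about 12724 genes, with 200 genes changed in each. The limma test recovered 23.4% of genes changed 1.5-fold, 59.7% of genes changed 2-fold and 91.4% of genes changed 4-fold, and 7.94% of its calls were false. False calls were 8.83% for edgeR, 10.3% for limma with the block and 23.0% for DESeq2, which ran on 15862 genes. The limit set on false calls in this check was dropped for DESeq2 after its rate was seen, and its counts should be read with that rate. Camera called 3 of 3 lists that had been moved and 0 of 30 that had not. Changed genes were drawn from those with an expected count of at least 50, and every gene of a moved list was raised 1.5-fold. Recovery of genes with fewer reads, or of lists with smaller changes, was thus not measured. The simulated genes were drawn independently of one another and without pair effects. The check thus does not cover the block on paired samples. Nor does it cover lists of correlated genes, where the correlation estimated from the 6 libraries reached 0.874 (ribosomal proteins).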

Results

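Microglia, the resident macrophages of the brain, can store neutral lipids in droplets. The series sorted hippocampal microglia of LPS-treated mice by their droplet load, and the comparison asks how the transcriptome of BODIPY-high microglia differed from that of BODIPY-low microglia. Each gate had 3 libraries of 34899413 to 39220494 recovered reads. BODIPY-low libraries held reads of 14031 to 14193 genes and BODIPY-high libraries of 14590 to 15088 genes. Ctsd, a lysosomal protease, was the most abundant gene of every library, with 2.66 to 3.29% of reads. Across genes, log2 values correlated at 0.964 to 0.970 between libraries of a gate and at 0.919 to 0.957 between gates. Genes are not independent replicates, so these coefficients describe the libraries only.

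**Figure D1:**
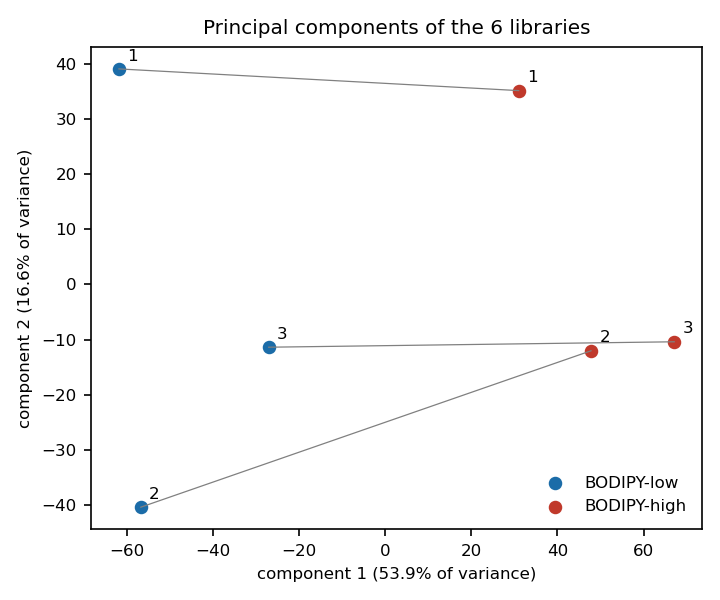
Principal components of log2 normalized counts, 1 point per library, with BODIPY-low in blue, BODIPY-high in red, and a line joining libraries of the same number. The first axis (53.9% of the variance) parts the gates, and the other axis (16.6%) sets both libraries of number 1 apart from the other 4.

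BODIPY-high microglia differed from BODIPY-low microglia mainly in genes that were close to silent in the low gate. Of 12767 genes tested, 259 rose and 3 fell in BODIPY-high libraries (limma, adjusted p under 0.05). Of the genes that rose, 233 did so more than 4-fold, and 200 had a mean of under 50 normalized counts in the low gate. Their median level in the low gate was 5.95 normalized counts, against 688 for all genes tested. Together they made up 0.249% of the normalized counts of tested genes in the low gate and 0.769% in the high gate. All 259 were higher in 3 of 3 pairs of libraries of the same number, a count nearly fixed by their selection on the same libraries. Of 98 markers of other cell types tested, 25 rose, against 259 of all 12767 genes tested. These markers were 9.65% of the 259 genes, a share limited by the length of the lists. Of the 259, 221 lay on no list, so the cell type they came from was not assigned.

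With the replicate block the counts were 558 higher and 59 lower, including 258 of the 259 and all 3 of the genes above. Without BODIPY-high library 2, 15 genes were higher; without BODIPY-high library 3, 59; without BODIPY-high library 1, 169. The counts were 135 without BODIPY-low library 1 and 117 without BODIPY-low library 2, and leaving out any 1 of these 5 libraries left 0 genes past the limma test as lower, while 1050 to 1357 genes in either direction had an unadjusted p under 0.05. On recovered reads, edgeR called 222 genes higher and 1 lower, and DESeq2 519 higher and 29 lower.

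Markers of the choroid plexus, the epithelium that makes cerebrospinal fluid, showed the largest rise of the lists. All 5 tested members rose, and the median log2 change was 5.84 (camera adjusted p = 7.23e-14; adjusted p = 0.288 with an estimated correlation). All 5 also passed when adjusted over the list alone. Transthyretin (Ttr, a thyroid hormone carrier, chromosome 18, 20665280 to 20674321) went from 352 ± 347 to 13980.0 ± 3517 normalized counts (SD, n = 3 per gate), which is 39.8-fold. The lysophospholipase D autotaxin (Enpp2, chromosome 15, 54838901 to 54952892) went from 576 ± 666 to 30271 ± 3866, or 52.6-fold. The folds depended on BODIPY-low library 3, which held more of both: without it they were 92.3-fold for Ttr and 157-fold for Enpp2, and those of Clic6 and Kcnj13 went from 42.8 and 57.2 to 70.7 and 114. The chloride channel gene Clic6, the potassium channel gene Kcnj13 and the folate receptor gene Folr1 rose as well, from 13.9 to 21.2 normalized counts in the low gate to 448 to 905 in the high gate. Adjusted p for the 5 genes lay between 0.00218 and 0.029, and Ttr, Enpp2, Clic6 and Kcnj13 still passed when any 1 library was left out.

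The 12 genes of largest rise were taken by the rule for named genes. The semaphorin gene Sema3b had 1 read over the 3 BODIPY-low libraries and 576 over the BODIPY-high libraries, a ratio of 528 corrected for library scaling (exact 95% counting interval 94.4 to 20883). The protease inhibitor gene A2m had 2 reads against 630, and the tight junction gene Cldn2 2 against 616. The water channel gene Aqp1 had 5 against 417 and the sulfate transporter gene Slc13a4 10 against 761. Vat1l had the largest fitted log2 change, 7.41 ± 0.83 (SE, adjusted p = 0.00493). The others were the sugar transporter gene Slc2a12, the Wnt and BMP antagonist gene Sostdc1, the sulfatase gene Sulf1, the potassium channel subunit gene Kcne2, the collagen gene Col8a2 and Enpp2. All 12 rose in 3 of 3 pairs, which the rule's condition of no overlap between gates fixes in advance. Their adjusted p ran from 0.00218 (Sema3b, A2m, Cldn2) to 0.03 (Sulf1). Without BODIPY-high library 2, Sema3b, A2m, Cldn2 and Enpp2 still passed and the other 8 did not (adjusted p up to 0.147). Sostdc1 was also lost without BODIPY-high library 3, and Sulf1 and Kcne2 without any 1 library other than BODIPY-low library 3. The ratios of the means of Slc13a4, Slc2a12, Sostdc1, Sulf1 and Col8a2 were 27.0 to 69.4, and 229 to 361 without BODIPY-low library 3. That of Cldn2 was 277, and 185 without BODIPY-low library 2. All BODIPY-low reads of Sema3b, Aqp1, Vat1l and Kcne2 were in BODIPY-low library 3, so without it their ratios have no finite value.

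Border-associated macrophage markers, genes of the macrophages that line the meninges and vessels, rose together. Of 12 tested, 9 passed (11 adjusted over the list alone), with a median log2 change of 3.66 (camera adjusted p = 5.45e-18; adjusted p = 0.352 with an estimated correlation). The mannose receptor gene Mrc1 (chromosome 2, 14229392 to 14332057) went from 1111 ± 812 to 12226 ± 9467 normalized counts, or 11.0-fold (adjusted p = 0.0202). The coagulation factor gene F13a1 rose 14.9-fold to 10580.3 ± 7128 (adjusted p = 0.0136) and the hyaluronan receptor gene Lyve1 38.9-fold to 617 ± 413 (adjusted p = 0.00805). Dab2, Colec12, Cd163, Folr2, Ms4a7 and Cbr2 were the other members past the test, and with the replicate block Clec10a and Pf4 passed too. Without BODIPY-high library 2, Mrc1, F13a1, Lyve1, Dab2 and Colec12 did not pass (adjusted p of 0.0566 to 0.102). Without BODIPY-high library 3 the folds of Dab2 and Colec12 went from 6.07 and 24.6 to 3.94 and 12.2. The folds of Mrc1, F13a1 and Lyve1 were 19.0, 29.2 and 96.6 without BODIPY-low library 3 and 6.11, 9.13 and 24.0 without BODIPY-high library 3. Mrc1 was also lost without BODIPY-low library 1, and Mrc1 and Dab2 without BODIPY-low library 2. The median deviation of the list from its mean over libraries was 3.21 in BODIPY-high library 3, against 0.92 and 1.36 in the other BODIPY-high libraries, and -0.57 in BODIPY-low library 3, against -2.50 and -2.44.

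Glial markers rose in part. Of 9 astrocyte markers, 4 passed (8 adjusted over the list alone), with a median of 1.85 (camera adjusted p = 1.26e-10; adjusted p = 0.231 with an estimated correlation): the secreted chaperone clusterin (Clu, 65.8 ± 42.7 to 1864 ± 519.8), Aldoc, Atp1b2 and Aldh1l1. With the replicate block Gfap and Gja1 of that list passed too (6 in all). Of 8 oligodendrocyte markers, 2 passed (5 adjusted over the list alone), among them the chaperone gene Cryab (3 with the block, adding Mobp), and the list median was 1.37 (camera adjusted p = 1.61e-05; adjusted p = 0.507 with an estimated correlation). That median was 0.58 without BODIPY-high library 3 and 2.12 without BODIPY-high library 1. Of 5 markers of oligodendrocyte precursors, 2 passed (4 adjusted over the list alone), with a median of 3.42 (camera adjusted p = 1.61e-05; adjusted p = 0.352 with an estimated correlation). The growth factor receptor gene Pdgfra had 0 reads in the low gate and 70 in the high gate, and Olig1 had 4 against 210. For Pdgfra this was 21.4-fold over a floor of 3 reads in the group, with an exact 95% lower limit of the ratio of 16.9. Clu and Aldoc passed when any 1 library was left out. The fold of Clu went from 28.3 to 45.1 without BODIPY-low library 3, and those of Atp1b2 and Olig1 from 12.6 and 47.2 to 8.22 and 25.6 without BODIPY-high library 3. Of the 4 Olig1 reads of the low gate, all were in BODIPY-low library 3. Aldh1l1 and Cryab were lost without BODIPY-low library 1 or 2 or BODIPY-high library 2 or 3, and Atp1b2, Pdgfra and Olig1 without any 1 library other than BODIPY-low library 3 (adjusted p up to 0.157).

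The remaining marker lists were not called. No tested member passed limma among 12 endothelial (list median 0.14, camera adjusted p = 0.872), 6 neuron (0.25, 0.764), 10 monocyte (0.09, 0.331), 13 neutrophil (0.05, 0.278) or 8 dendritic cell markers (0.04, 0.818). At an unadjusted p under 0.05, 1, 1, 2, 3 and 0 members of these lists were higher and 0 lower, and edgeR called 0 and DESeq2 1, a neutrophil gene. The monocyte list was called without BODIPY-high library 1 (median 0.51, camera adjusted p = 0.0138) and the neutrophil list without BODIPY-high library 2 (0.18, 0.00827). With the replicate block, 1 monocyte gene, 2 neutrophil genes (Mmp9 and Retnlg) and 1 dendritic cell gene (Cd209a) passed as higher. Of lists too short for the set test, Cd4 was the 1 member past the test of 3 T and NK cell genes (24.2 ± 37.4 to 679.6 ± 687). Vtn was that of 4 mural cell genes, and the heme synthesis gene Alas2 that of 2 erythroid genes (56.6 ± 53.4 to 965 ± 555), where both passed adjusted over the list alone, and both with the block (Slc4a1, adjusted p = 0.00757). The folds of Cd4 and Alas2, 28.0 and 17.0, were 254 and 37.3 without BODIPY-low library 3, and that of Cd4 was 11.7 without BODIPY-high library 3. Alas2 was lost without BODIPY-low library 2 or BODIPY-high library 2 or 3, Cd4 without any 1 library other than BODIPY-low library 3 and Vtn without any 1 other than BODIPY-low library 1 (adjusted p up to 0.176). The single tested B cell marker, Cd79b, did not pass (adjusted p = 0.578).

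**Figure D2:**
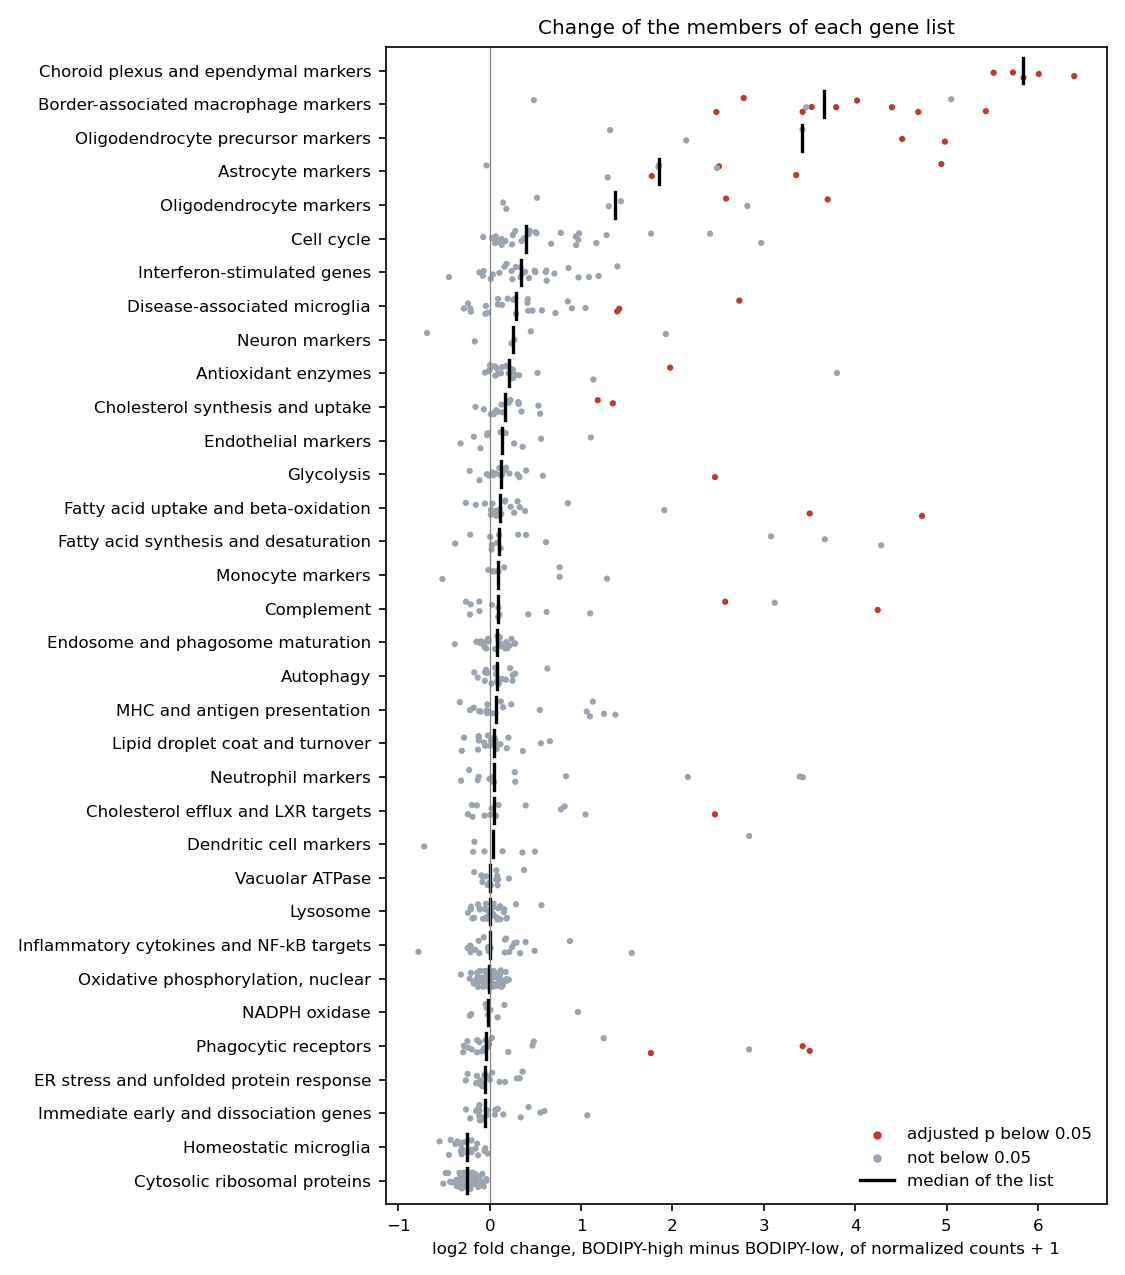
Log2 fold change of every tested member of the 34 lists, BODIPY-high minus BODIPY-low, with red points for members of adjusted p under 0.05 and a black bar at the list median. Medians run from 5.84 for choroid plexus markers to -0.25 for ribosomal proteins, and no red point lies below 0.

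Genes of the lipid droplet itself did not pass the test. Of 24 tested members of the droplet coat and turnover list, 0 were called at an adjusted p under 0.05 by limma, and the median log2 change was 0.05 (camera adjusted p = 0.756). At an unadjusted p under 0.05, 3 members were higher and 0 lower, while edgeR called 0 and DESeq2 1 higher. Perilipin 2 (Plin2, the droplet coat protein, chromosome 4, 86648386 to 86670060) had 2191 ± 140.2 normalized counts in the low gate and 2851 ± 556 in the high gate (log2 change 0.36 ± 0.14, SE; adjusted p = 0.407). Perilipin 3 (Plin3, chromosome 17, 56277476 to 56292873) had 839 ± 135 and 1338 ± 333 (adjusted p = 0.194), and it passed with the replicate block (adjusted p = 0.0124). The triglyceride synthesis gene Dgat2 (0.19, adjusted p = 0.93), the acyl-CoA synthetase gene Acsl1 (0.06, 0.929) and the acetyl-CoA transporter gene Slc33a1 (-0.06, 0.948) differed by less than their standard errors of 0.12 to 0.37.

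Among genes of fatty acid uptake and beta-oxidation, 2 of 25 rose, also when adjusted over the list alone. The scavenger receptor and fatty acid transporter gene Cd36 (chromosome 5, 17781690 to 17888801) went from 183 ± 123 to 1981 ± 1484 normalized counts (adjusted p = 0.0452). Ppargc1a, a coactivator of mitochondrial genes, had 1 read in the low gate and 102 in the high gate, a ratio of 93.5 (exact 95% counting interval 16.4 to 3727, adjusted p = 0.0176). That read was in BODIPY-low library 2, so without it the ratio has no finite value. The other members had small log2 changes, 22 of 25 positive, and the median was 0.11 (camera adjusted p = 0.000689; adjusted p = 0.435 with an estimated correlation). The ratio of the means of Cd36 was 10.8, and 6.33 without BODIPY-high library 3. Cd36 no longer passed without BODIPY-low library 1 or 2 or BODIPY-high library 2 or 3 (adjusted p up to 0.182), and Ppargc1a no longer passed without any 1 of the BODIPY-high libraries (up to 0.13).

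Among 22 genes of cholesterol synthesis and uptake, 2 rose, also when adjusted over the list alone. Squalene epoxidase (Sqle, chromosome 15, 59315077 to 59331192) went from 179.6 ± 11.8 to 409 ± 36.3 normalized counts (2.28-fold, adjusted p = 0.0194). Sqle was lost without BODIPY-low library 2 or any 1 BODIPY-high library (adjusted p up to 0.124). The list median was 0.17 (camera adjusted p = 0.0123; adjusted p = 0.575 with an estimated correlation), and the list was not called without BODIPY-low library 2 or BODIPY-low library 3 (camera adjusted p = 0.0926 and 0.102). Its median was 0.29 without BODIPY-low library 1 and 0.26 without BODIPY-high library 1. Of 14 cholesterol efflux and LXR target genes, the phospholipid transfer gene Pltp rose (526 ± 155 to 3359.7 ± 2500.1, adjusted p = 0.0304), and 2 members passed adjusted over the list alone. The fold of Pltp was 6.39, and 3.68 without BODIPY-high library 3. Pltp was lost without any 1 BODIPY-low library or BODIPY-high library 2 (adjusted p up to 0.125). That list was not called (median 0.04, camera adjusted p = 0.278). Apolipoprotein E (Apoe, chromosome 7, 19696109 to 19699188), the main lipid carrier of the brain, had 191968 ± 59118 and 418992 ± 223394 normalized counts. It did not pass (log2 change 1.05 ± 0.35, SE; adjusted p = 0.284), and passed with the replicate block (adjusted p = 0.00105). Fatty acid synthesis genes had 0 of 15 members past the limma test (3 adjusted over the list alone), a median of 0.10 and a camera adjusted p of 0.0502. Of its members, 4 were higher at an unadjusted p under 0.05, while edgeR called 0 and DESeq2 2. The list was called without BODIPY-low library 1 (camera adjusted p = 0.00391) and without BODIPY-high library 3 (0.0385). With the block, Fads2 and Me1 of that list passed.

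In the same libraries in which Cd36, Pltp and Apoe were higher, border-associated macrophage markers were higher too, with the highest values of each in BODIPY-high library 3. Sqle and Lpl had values of similar size in all 3 BODIPY-high libraries.

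**Figure D3:**
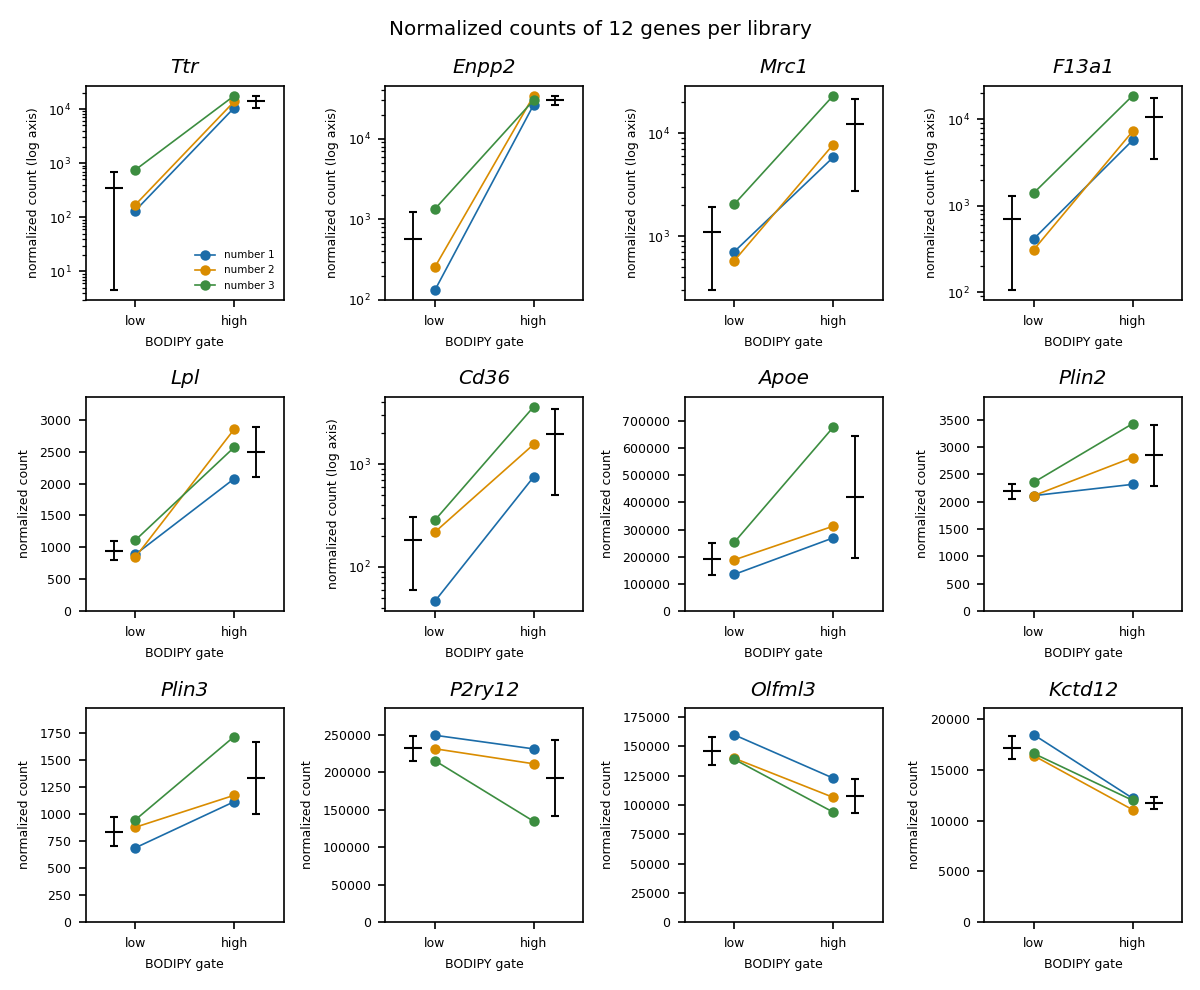
Normalized counts of 12 genes in each library, with lines joining libraries of the same number and black marks for the gate mean and SD (n = 3); 5 panels have log axes and the others start at 0. Ttr, Enpp2, Mrc1, F13a1, Lpl and Cd36 passed as higher and Kctd12 as lower, while Apoe, Plin2, Plin3, P2ry12 and Olfml3 did not pass.

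Genes of the homeostatic microglial state were slightly lower as a list. None of the 22 members had a positive log2 change and the median was -0.24 (camera adjusted p = 5.97e-06; adjusted p = 0.507 with an estimated correlation). No member passed limma over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 4 were lower and 0 higher, while edgeR called 0 and DESeq2 3 lower. Log2 changes of the canonical markers were -0.29 for Tmem119, -0.31 for the purinergic receptor gene P2ry12 and -0.30 for the fractalkine receptor gene Cx3cr1 (adjusted p = 0.667, 0.713 and 0.819). The extracellular protein gene Olfml3 had the lowest p of the list (adjusted p = 0.217). With the replicate block, Olfml3, Sparc, Slc2a5 and Rhob passed as lower (12 members adjusted over the list alone). Without BODIPY-high library 3 the list median was -0.096 and the list was still called.

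Genes of the disease-associated state, a program described in microglia near plaques and dying neurons, were higher as a list, with 3 of 26 past the test (4 adjusted over the list alone). The median was 0.28 (camera adjusted p = 0.000662; adjusted p = 0.507 with an estimated correlation). Lipoprotein lipase (Lpl, chromosome 8, 68880491 to 68907448), which frees fatty acids from lipoproteins, went from 949 ± 144 to 2502 ± 393 normalized counts (2.64-fold, adjusted p = 0.00493). The growth factor gene Igf1 went from 98.2 ± 37.4 to 713 ± 417 (adjusted p = 0.0202) and the inhibitory receptor gene Lilrb4a from 648 ± 174 to 1778 ± 643 (adjusted p = 0.0478). Trem2, the lipid-sensing receptor of this state, had 48227 ± 2839 and 39630.4 ± 958 (log2 change -0.28, adjusted p = 0.278). With the replicate block 8 members passed as higher, adding Apoe, Ank, Itgax, Clec7a and Axl. Lpl no longer passed without BODIPY-high library 2 (adjusted p = 0.0522), Igf1 and Lilrb4a not without BODIPY-low library 1 or 2 or BODIPY-high library 2 or 3 (up to 0.212), and the list median was 0.43 without BODIPY-high library 1.

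No cytokine gene passed the test at this sample number. None of 26 inflammatory cytokine and NF-kB target genes passed limma, over all genes or adjusted over the list alone; 4 were higher and 2 lower at an unadjusted p under 0.05, and edgeR and DESeq2 called 0. The list median lay just below 0 and its mean at 0.11 (camera adjusted p = 0.798). Il1b had 579.8 ± 77.1 and 652 ± 107 normalized counts (adjusted p = 0.852), Tnf 133 ± 24.0 and 187 ± 30.2 (0.595), and Il6 167 ± 8.13 and 96.8 ± 2.58 (0.23). With the block, Ccl3 alone of this list passed. Interferon-stimulated genes were higher as a list, with 24 of 28 positive and a median of 0.35 (camera adjusted p = 0.000346; adjusted p = 0.694 with an estimated correlation). No member passed limma over all genes or over the list alone, 7 were higher at an unadjusted p under 0.05, and edgeR called 0 and DESeq2 2, while 8 passed with the replicate block, Irf7 (adjusted p = 0.00707), Oas1a, Oas2 and Rsad2 among them. Without BODIPY-low library 1 the list was not called (median 0.14, camera adjusted p = 0.101), and without BODIPY-high library 1 its median was 0.58. Its median deviation was highest in BODIPY-high library 3 (0.47, against -0.24 and 0.30 in BODIPY-high libraries 1 and 2). Those of border-associated macrophage markers (3.21) and monocyte markers (0.94) were highest there too. So were those of the inflammatory, autophagy, vacuolar ATPase and NADPH oxidase lists, which were not called. Those of the lipid droplet and lysosome lists were highest in BODIPY-high library 2.

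Of 15 complement genes, 2 rose (5 adjusted over the list alone): Cd55, which limits complement activation on cell surfaces (64.8 ± 33.2 to 1369 ± 1061, adjusted p = 0.0117), and properdin (Cfp), which promotes it (257 ± 54.0 to 1740.0 ± 1092, adjusted p = 0.0168). The list was not called by camera (median 0.09, adjusted p = 0.0561), while fry without the block called it higher (adjusted p = 0.00443). Camera called it with the block (adjusted p = 0.0146, and 0.375 with an estimated correlation), where C4b, C3 and Itgax passed too. Camera also called the list without BODIPY-low library 1 (adjusted p = 0.0422) and without BODIPY-high library 3 (0.021). Values of Cd55, Cfp, C4b, C3, Cd74, H2-Aa, H2-Ab1 and H2-Eb1 were highest in BODIPY-high library 3, as were those of border-associated macrophage markers, and the increments of C4b over the 3 pairs kept close to those of the markers (SD of the log2 ratio 0.135, against 0.384 for Cd74 and 0.399 for H2-Aa). Without BODIPY-high library 3 the folds of Cd55 and Cfp went from 21.1 and 6.76 to 11.9 and 4.42. Cd55 was lost without BODIPY-high library 2, and Cfp without BODIPY-high library 2 or BODIPY-low library 1 or 2 (adjusted p up to 0.104). None of 19 MHC and antigen presentation genes passed limma, over all genes or over the list alone (median 0.07, camera adjusted p = 0.658), and the list was called without BODIPY-high library 1 (0.17, 0.0349). In that list 1 gene was higher and 1 lower at an unadjusted p under 0.05, and edgeR called 0 and DESeq2 1 lower. With the block, the class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1 passed as higher and H2-DMa as lower. Of 24 phagocytic receptor genes, 3 rose (3 higher and 1 lower adjusted over the list alone), Msr1 (510.3 ± 105 to 1784 ± 616, adjusted p = 0.0138), Mrc1 and Cd36. That list was not called, with a median of -0.04 and a mean of 0.50 (camera adjusted p = 0.798), and with the block 6 members passed as higher and Fcgr1 as lower. Msr1 was lost without BODIPY-low library 2 or BODIPY-high library 2 (adjusted p up to 0.0927), Mrc1 without BODIPY-low library 1 or 2 or BODIPY-high library 2, and Cd36 without those or BODIPY-high library 3 (up to 0.182). Mrc1 is also among the border-associated macrophage markers, which rose in the same libraries.

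No list of degradation pathways was called in the main test, while the endosome and autophagy lists were called higher after quantile normalization (camera adjusted p = 0.0367 for both). No member passed limma, over all genes or adjusted over the list alone, among 33 lysosomal genes (median 0.01, camera adjusted p = 0.998), 16 vacuolar ATPase genes (0.01, 0.756), 25 endosome and phagosome genes (0.08, 0.278), 21 autophagy genes (0.08, 0.187) or 9 NADPH oxidase genes (-0.02, 0.798). At an unadjusted p under 0.05, 1, 2, 3, 1 and 1 members of these lists were higher and 1 lysosomal gene lower, while edgeR called 0 and DESeq2 1 vacuolar ATPase gene. Progranulin (Grn, a lysosomal regulator) had 229386 ± 18250.3 and 235487 ± 31027 normalized counts (adjusted p = 0.975). With the block, Atp6v1a (adjusted p = 0.0158) and Cybb, the catalytic subunit of the NADPH oxidase (adjusted p = 0.00257), passed as higher.

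Antioxidant enzyme genes were higher as a list, with 22 of 24 positive and a median of 0.21 (camera adjusted p = 0.000689; adjusted p = 0.694 with an estimated correlation). The glutathione transferase gene Gsta4 passed (27.5 ± 9.96 to 109 ± 26.4, adjusted p = 0.0475), 3 members passed adjusted over the list alone, and Nqo1, Gstm1 and Hmox1 also passed with the block. Catalase (Cat), which breaks down peroxide, had 4299 ± 77.9 and 5086 ± 818 (adjusted p = 0.594). The list was not called without BODIPY-low library 1 (median 0.093, camera adjusted p = 0.0899) or without BODIPY-high library 3 (0.092, 0.0743). The list median was highest in BODIPY-high library 3, as was that of border-associated macrophage markers (deviations of 0.31 and 3.21), and so were Gstm1 and Hmox1. Medians of several uncalled lists were highest there too, so this order does not tie the list to those markers. Gsta4 was lost without any 1 library other than BODIPY-low library 3 (adjusted p up to 0.246). Glycolysis genes had a median of 0.13 (camera adjusted p = 0.0101, and 0.526 with an estimated correlation). Their median deviation, too, was highest in BODIPY-high library 3 (0.16, against -0.005 and 0.072 in BODIPY-high libraries 1 and 2). Phosphofructokinase P (Pfkp) rose from 101 ± 44.2 to 557 ± 228 (adjusted p = 0.0283), the 1 of 18 members past the test (2 adjusted over the list alone), and Pkm passed with the block. Without BODIPY-low library 2 that list was not called (camera adjusted p = 0.0924), and Pfkp was lost without BODIPY-low library 1 or 2 or BODIPY-high library 2 or 3 (adjusted p up to 0.151). None of 74 nuclear genes of oxidative phosphorylation passed limma, over all genes or over the list alone, or had an unadjusted p under 0.05, and edgeR and DESeq2 called 0 (median -0.01, camera adjusted p = 0.756). That list was called lower without BODIPY-low library 1 (-0.14, camera adjusted p = 0.000186) and without BODIPY-high library 3 (-0.11, 0.0218), and higher without BODIPY-low library 3 (0.14, 0.00704).

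Cytosolic ribosomal protein genes were lower as a list: none of 75 had a positive log2 change and the median was -0.25 (camera adjusted p = 2.07e-11; adjusted p = 0.694 with an estimated correlation). No member passed limma, over all genes or adjusted over the list alone, 1 was lower at an unadjusted p under 0.05, edgeR and DESeq2 called 0, and Fau passed as lower with the block. The median was -0.092 without BODIPY-low library 3, -0.16 without BODIPY-high library 2, -0.40 without BODIPY-low library 1 and -0.41 without BODIPY-high library 3. Cell cycle genes had 31 of 32 positive changes and a median of 0.40 (camera adjusted p = 0.0167; adjusted p = 0.866 with an estimated correlation), with no member past limma, over all genes or over the list alone. Only 2 were higher at an unadjusted p under 0.05, and edgeR and DESeq2 called 0. With the block, Cenpf, Bub1, Rrm2, Nusap1 and Ccna2 passed as higher. The list was not called without BODIPY-low library 1 (median -0.048) or BODIPY-high library 2 (median -0.22, camera adjusted p = 0.522), and its median was 1.07 without BODIPY-high library 1 and 0.98 without BODIPY-low library 2. Neither 21 genes of endoplasmic reticulum stress (median -0.05, camera adjusted p = 0.278) nor 22 immediate early genes (-0.06, 0.798), which respond to cell dissociation, held a member past limma, over all genes or over the list alone. At an unadjusted p under 0.05, 1 and 2 were higher and 1 and 1 lower, and edgeR and DESeq2 called 0. Without BODIPY-high library 3 the immediate early list was called lower (median -0.35, camera adjusted p = 0.000173).

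The 3 genes that fell were expressed at high levels in both gates and changed little. Kctd12 (chromosome 14, 102976581 to 102982637) went from 17155 ± 1136 to 11757 ± 604 normalized counts (log2 change -0.54, adjusted p = 0.0216). The store-operated calcium channel gene Orai1 (chromosome 5, 123015074 to 123030456) went from 9211 ± 256 to 6936 ± 241 (-0.41, adjusted p = 0.0409), and Fam212a from 4526 ± 137 to 3329 ± 246 (-0.45, adjusted p = 0.0499). The 5 next genes did not pass: Gp9, Kdelr2, Bmf, Ndnl2 and Tram2 had log2 changes of -0.45 (Kdelr2) to -1.22 (Tram2) and adjusted p of 0.0626 to 0.1, and all 5 passed with the replicate block. When 1 library was left out, Kctd12 passed only without BODIPY-low library 3 (adjusted p up to 0.125 otherwise), and Orai1 and Fam212a did not pass whichever of the 6 was left out (up to 0.194).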

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

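Thinned reads, the test without markers of other cells, the replicate block with a number left out, and the block with an estimated correlation or fry were chosen after seeing the data. The 259 genes higher and 3 lower stayed within 1.5 times under other pseudocounts, no filter, TMM rescaling, thinned reads and without markers of other cells. A minimum of 50 gave 131 higher and 1 lower, with fewer genes tested (10918). Quantile normalization gave 139 and 1, limma without a trend 159 and 5 (140 and 0 of them shared), library weights 5 lower, edgeR 1 lower and DESeq2 519 higher and 29 lower; the cause was not tested.

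The replicate block gave 558 higher and 59 lower with limma, 499 and 50 with edgeR, and 710 and 144 with DESeq2. With the replicate block and 1 number left out, limma gave 279 to 702 higher and 21 to 80 lower (33 without number 2). Among the named genes the block added 35 calls and removed 0, and among lists it added complement and removed 0.

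Leaving out 1 library or both of a number gave 0 to 271 higher and 0 to 2 lower. The 0 was limma without both libraries of number 2, where 815 genes had an unadjusted p under 0.05. These runs kept the genes tested with all libraries. They were first run with the filter applied anew, which dropped genes by construction and gave 0 to 277 higher; this was changed after the results were seen. Fewer samples remain in each of these runs.

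Of the 34 lists, 14 passed, and 12 to 19 under settings that kept the preset correlation. Calls gained with all libraries included fatty acid synthesis (pseudocount 5, no filter, TMM, quantile, edgeR), complement (quantile, block), endosome and autophagy (quantile) and neuron markers (no filter). Runs without 1 library also called nuclear oxidative phosphorylation, MHC, monocyte, neutrophil, immediate early, fatty acid synthesis or complement lists, as given above. The highest count, 19, came from the block without number 1. An estimated correlation left 0, the replicate block with an estimated correlation 0, and fry with the replicate block 9. Fry without the block left 4: the complement, astrocyte, oligodendrocyte precursor and choroid plexus lists (adjusted p of 0.00443 to 0.0111). Among lists called by camera, fry did not call border macrophage (0.0766), homeostatic (0.339), disease-associated (0.209), interferon (0.468) or ribosomal protein (0.541) genes. Over all settings, 782 list values kept direction and side of the threshold, 58 lost and 39 gained the call, and 2 reversed. The nuclear oxidative phosphorylation median ran from -0.14 to 0.14 when a library was left out, the cell cycle median from -0.22 to 1.07; the cause was not tested. For named genes, 4123 values kept direction and side, 296 lost and 232 gained the call, and 0 reversed. Sign changes where neither value passed count as kept (68 for lists, 41 for genes). The share of mitochondrially encoded genes was not run. Depth limits genes near the floor of 3 reads.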

Other observations

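Of the tests of explanations, the correlation of the border macrophage and choroid plexus lists over libraries was chosen before its result was seen; thinning, the comparison with endothelial markers, the random lists, the ratios of increments, quantile normalization as a test of the homeostatic pattern, the order of pairs and the splits were put to these patterns only after the results were seen.

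Some genes that rose already had high values in the BODIPY-low libraries. Of the 259 genes, 8 had a mean of at least 1000 normalized counts in the low gate, singled out after their values were seen. The macrophage surface receptor gene Adgre1 went from 59298 ± 3581 to 92349 ± 10685 (SD, n = 3, limma adjusted p = 0.0339), the adhesion gene Vcam1 from 3343 to 5553 (adjusted p = 0.0393) and the transporter gene Slc22a17 from 1206 ± 70.2 to 2142 ± 134 (adjusted p = 0.00888). Aplp2, Stom, Clic4, Dab2 and Mrc1 were the others, and all 8, like all 259 genes, were higher in 3 of 3 pairs. Dab2 and Mrc1 are border-associated macrophage markers. Mrc1 had 2046 normalized counts in BODIPY-low library 3, against 709 and 579 in BODIPY-low libraries 1 and 2. Programs also differed between libraries of a gate. The median deviation of cell cycle genes was -1.34, 0.87 and -0.21 in BODIPY-low libraries 1, 2 and 3 and -1.06, 1.86 and 0.08 in BODIPY-high libraries 1, 2 and 3.

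Markers of choroid plexus, border-associated macrophages and other glia were higher in the BODIPY-high libraries. Depth as the whole cause was argued against. After reads were thinned to the smallest library, the choroid plexus median was 5.79 and the border macrophage median 3.64. A lower share of microglia that raises all other cells alike was not decided. The choroid plexus median lay 5.70 above the endothelial one (95% bootstrap interval over genes 5.35 to 6.28), but genes of a list are correlated. Of 12 endothelial markers, 7 had at least 50 normalized counts in every BODIPY-low library, which limits the log2 change that added RNA can give. Cells or RNA of the choroid plexus, border-associated macrophages or other glia may be the source (Ttr reached 13980.0 and Mrc1 12226 normalized counts). Around the gate means, border macrophage and choroid plexus markers each moved together more than all 1000 random lists matched on expression (percentile 100). With the pairs removed the mean correlation was 0.79 for choroid plexus (percentile 99.6) and 0.065 for border macrophage markers (80.7), so this source stays open. The gate on CD11b and low CD45 would remove epithelium, glia and macrophages high in CD45, and of 12 border macrophage and 5 choroid plexus markers, 7 and 2 had at least 50 normalized counts in every BODIPY-low library. Expression of these genes by the microglia themselves stays open: the 2 lists correlated at 0.76 over the libraries (p = 0.1111, smallest possible 0.0278), so it cannot be told apart with 6 libraries.

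The 9 lipid and phagocyte genes that passed, leaving out Mrc1, which is a border macrophage marker itself, among them Ppargc1a, Cd36, Sqle, Pltp, Lpl, Igf1, Lilrb4a and Msr1, rose along with those markers. For 8 of 9, the increments over the 3 pairs kept their ratio to the border macrophage markers within the widest SD among the markers (1.31), so RNA of border macrophages may be a source of some of them, with the lowest SD for Cd36 (0.24) and Pltp (0.25). Sqle and Lpl kept a closer ratio to the choroid plexus markers (SD 0.19 and 0.199, against 0.966 and 1.27 to the border macrophage markers), within the widest SD of the choroid plexus markers (0.232). Lilrb4a, Msr1 and Ppargc1a were closer to the choroid plexus markers too (0.417, 0.424 and 0.618, against 0.773, 0.714 and 1.58). The choroid plexus index varied less over pairs 1, 2 and 3 (2031, 3002 and 2869.5) than the border macrophage index (911, 1407 and 4872). Genes with steady increments thus lie closer to choroid plexus markers whatever their source, and no share of unchanged genes was computed for that bound. The comparison does not decide the source of these 5 genes. The border macrophage bound is wide: 37.9% of 1365 unchanged genes also lay within it, and 0 of the 9 genes lay within the median SD of the border macrophage markers (0.214). Ppargc1a lay outside (SD 1.58). Its increments were 41.0, 31.9 and 25.7 normalized counts in pairs 1, 2 and 3, an order opposite to that of the border macrophage index. These are few reads of 1 gene, so they decide nothing for the other genes. Expression by lipid-laden microglia themselves stays open, untested.

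The homeostatic and ribosomal protein lists were lower in the BODIPY-high libraries. A shift of the normalization common to all genes was argued against as the whole cause. After quantile normalization the list medians were -0.18 and -0.25, against -0.047 for all genes tested. Camera still called both (adjusted p = 0.00197 and 3.55e-08 at the preset correlation). It compares a list with all other genes, so a common shift could not have ended its call. With an estimated correlation, without quantile normalization, its adjusted p was 0.507 and 0.694. For dilution by RNA of other cells the pairs gave no single order: the homeostatic median was -0.40 in pair 3, which had the largest border macrophage increment, and -0.13 in each of the others. The choroid plexus increment was largest in pair 2 (index 3002, against 2031 and 2869.5 in pairs 1 and 3). The ribosomal median was lowest in pair 2 (-0.40, against -0.082 and -0.28). Its genes are not markers of microglia, so their order does not test dilution. Dilution thus stays open for the homeostatic list and untested for the ribosomal one. A change of state of the microglia stays open, untested.

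The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 262 genes and the highest of the others 0 (1 of 10 with as many, the real one). Of the others, 3 part all pairs as the real one does, and with the replicate block the real split gave 617 genes and these 3 gave 0, while the other 6 put both libraries of a pair in 1 group.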
